A study of Homo sapiens with 15 samples.

How the data were processed

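Gene expression was measured in MCF-7, a human breast cancer cell line of luminal type that carries the oestrogen receptor, on Affymetrix arrays that hold 54675 probe sets. The deposited table has 15 columns. Per the labels' protocols, cells were transfected with 1 of 3 siRNAs against AP-2γ (the transcription factor encoded by TFAP2C), with a non-silencing siRNA, or treated with transfection reagent alone, and there are 3 columns for each of these 5 conditions. siRNAs were used at 25 nM. The labels do not give the time between transfection and harvest. Total RNA was extracted, cleaned on a column with DNase and labelled with biotin, per the labels' protocols.

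The deposited values are log2 signals between 1.8 and 14.9, made by the authors with software that the submitters' processing notes name as affy, with no version and no further step. Background correction, normalization and summary of probes to probe sets are therefore not known beyond that name. No counts exist for arrays, so the number of arrays per condition limits the precision.

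The 3 reagent-only columns were found to be arithmetic means of non-silencing columns. Reagent-only column 1 equals the mean of non-silencing columns 1 and 2, column 2 the mean of non-silencing columns 2 and 3, and column 3 a mix of 75% of non-silencing column 1 and 25% of column 2. Each holds for all 54675 probe sets within a tolerance of 1e-08 on the log2 scale. The 15 columns have 12 independent dimensions. The reagent-only columns were left out of all results except 1 alternative. This departs from the design fixed before the data were examined, which had both controls. Genes called in all 6 comparisons became genes called in the 3 comparisons with the non-silencing siRNA, and the comparison of the controls was dropped.

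Symbols came from the platform annotation, updated by gene identifier with RefSeq names of the assembly GRCh38.p14. Of the probe sets, 41097 name a single gene, 1801 name several genes and 11777 name no gene or are not listed, and 41043 of the first kind matched a RefSeq gene identifier. For each of the 19775 genes the probe set with the highest mean over the arrays was taken. A gene was tested when its highest condition mean reached the 40th percentile of all probe set means, a log2 signal of 6.82, which left 15615 genes. Detection calls were not used here, so where a named gene lies below this level in 1 of the conditions compared, its change is treated as a lower bound in size. This is a precaution, as the level is a filter and not a detection limit. Of the tested genes, 5186 rest on probe sets whose suffix marks possible cross-hybridisation. The files name no genome build, so no coordinates are given, and no transcript sequence was available to place the siRNA targets or search for seed matches.

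Tests used limma 3.58.1 in R 4.3.3 with moderated variances and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p below 0.05. All 12 arrays entered a fit with a mean for each of the 4 conditions, which gave each siRNA against the non-silencing siRNA and an F test among the 3 siRNAs. The labels call the arrays of a condition technical replicates, so these p-values measure only the spread between arrays, which may be technical. Each gene has 1 spread over the 4 conditions, so the siRNA 3 arrays also enter the spread used for siRNA 1 and siRNA 2. Unequal spread between conditions was not modelled. For TFAP2C the SD was 0.14 with siRNA 3, against 0.63 and 0.71 with siRNA 1 and 2. A separate fit used the condition means, 3 siRNA conditions against the non-silencing condition, where the siRNA sequence is the replicate and the lone control is assumed to vary like the siRNA conditions. On these means 19 gene lists, fixed before the data were examined, were tested with camera at a preset correlation of 0.01, and again with an estimated correlation. Lists were also tested for each siRNA in the fit of arrays, a step added after the data were seen. Log2 changes are given with their standard error from the fit, and levels as mean ± SD over arrays.

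Named genes followed a rule fixed before the data were examined, except that its parts with the reagent-only control were left out. That change was made after the reagent-only columns were examined. The rule as changed is given here. It takes TFAP2C and CDKN1A, the 10 genes in each direction with the largest smallest change among those called with all 3 siRNAs, up to 4 members of each list, and up to 3 genes in each direction that passed for a single siRNA against the non-silencing siRNA and against both other siRNAs. A list with no called member in the fit of condition means contributes its 2 members with the largest change. Other list members named as examples were chosen after their values were seen.

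Replicate numbers are shared between conditions in the labels. Deviations of same-numbered arrays from their condition means correlated above 0.1 in 17 of 18 pairs. All 3 pairs did so for siRNA 1 with the non-silencing siRNA (0.45 to 0.71) and for siRNA 3 with it (0.16 to 0.50). For siRNA 2 with it the lowest was 0.07. All pairs among the 3 siRNAs did so too (0.14 to 0.72). Values from a fit with the replicate number as a block are therefore given beside siRNA 1 and siRNA 3 results and the F test among siRNAs where they change a call or move a count by more than 1.5 times.

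The scripts were tested on simulated data with 200 changed genes among the 15615. For siRNA 1 against the non-silencing siRNA, 50.7% of 1.5-fold changes, 89.6% of 2-fold changes and 100% of 4-fold changes were recovered. The fit of condition means recovered 0% of 1.5-fold, 11.9% of 2-fold and 71.2% of 4-fold changes. Alternatives covered normalization, filters, the choice of probe sets, the spread model, the replicate block, each array left out in turn, each siRNA left out in turn, fold thresholds and other gene list tests.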

Results

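Transcript levels were measured in MCF-7 cells transfected with siRNAs against AP-2γ. AP-2γ is a transcription factor that binds GC-rich promoter sequences and is found in many breast cancers. Silencing used 3 independent siRNAs, AAUGAGAUGGCAGCUAGGAAG (siRNA 1), GCGGCCCAGCAACUGUGUAAA (siRNA 2) and CCACACUGGAGUCGCCGAAUA (siRNA 3), and the control was the non-silencing siRNA AAUUCUCCGAACGUGUCACGU. Each condition had 3 arrays. The series also names a control with transfection reagent alone, but its 3 columns are arithmetic means of the non-silencing columns to within 6.5e-09 and carry no measurement of their own, so the results rest on 12 arrays.

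The array labelled replicate 1 stood apart from the others of its condition, most clearly with siRNA 1 and siRNA 2. The first principal component, with 44% of the variance, placed replicate 1 of siRNA 1 at -37.4 and replicate 1 of siRNA 2 at -38.3, while the other 10 arrays lay between -11.8 and 23.2. Hybridisation spike-ins, bacterial and phage transcripts added at known amounts, were lowest on replicate 1 in 4 of 4 conditions. The SD of log2 signal over probe sets was 1.41 and 1.44 on replicate 1 of siRNA 1 and siRNA 2, lower than on each of the other 10 arrays.

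**Figure D1:**
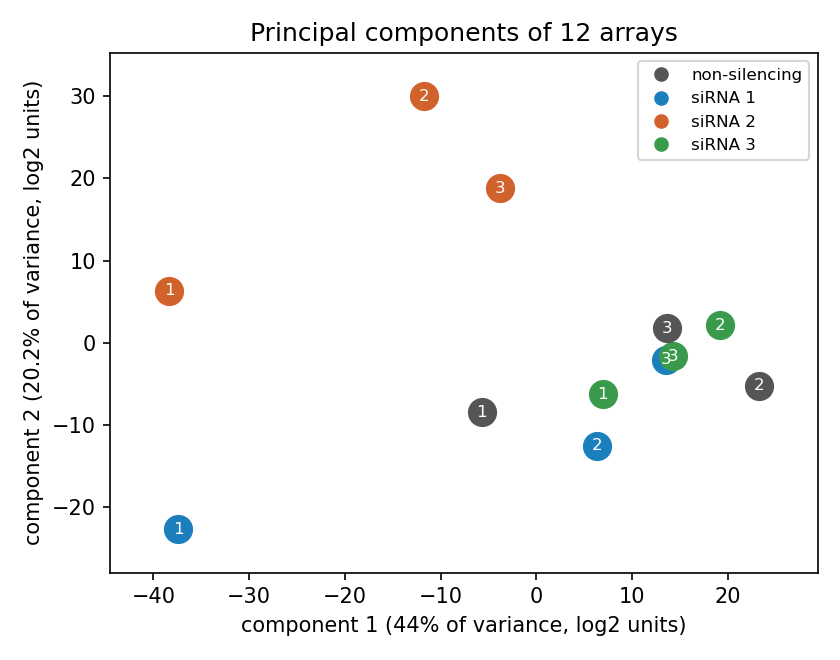
Scores of 12 arrays on the first and second principal components of 15615 genes (log2 units), coloured by condition and numbered by replicate. Replicate 1 of siRNA 1 and of siRNA 2 lie at -37.4 and -38.3 on the first component.

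TFAP2C, the targeted gene, was lowest with siRNA 2. Its brightest probe set read 10.90 ± 0.39 (SD, n = 3) with the non-silencing siRNA, 9.65 ± 0.63 with siRNA 1, 8.99 ± 0.71 with siRNA 2 and 10.24 ± 0.14 with siRNA 3. TFAP2C fell with siRNA 2 to 26.7% of the control (log2 change -1.90 ± 0.35, limma adjusted p = 0.00489). With siRNA 1 it was 42% of the control (-1.25 ± 0.35), with an adjusted p of 0.0724 that became 0.00152 with the replicate number as a block. With siRNA 3 it was 63.5% of the control (-0.65 ± 0.35, adjusted p = 0.585). All 3 arrays of each siRNA lay below all 3 non-silencing arrays, and the F test among siRNAs gave an adjusted p of 0.115 for TFAP2C, which became 0.00288 with the replicate block. A second probe set gave changes of -1.06, -1.61 and -0.54. CDKN1A, which encodes the cell cycle inhibitor p21, rose with siRNA 2 (0.73 ± 0.11, adjusted p = 0.00112) and was 0.15 ± 0.11 with siRNA 1 and 0.11 ± 0.11 with siRNA 3.

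**Figure D2:**
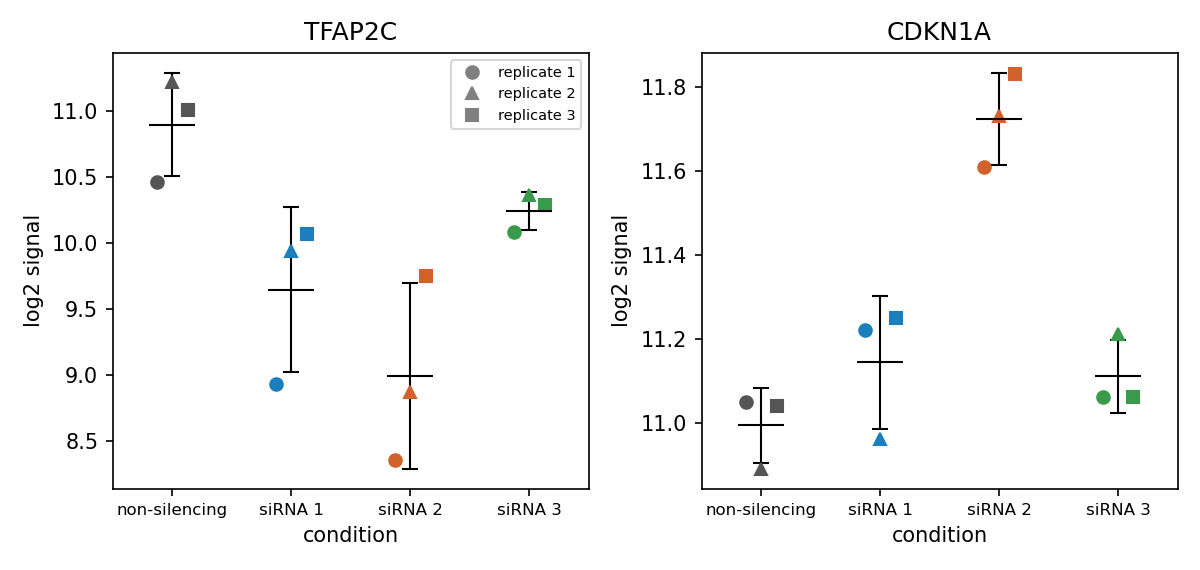
Log2 signal of TFAP2C and CDKN1A on each array by condition, with the mean and SD of 3 arrays as a line and bar and the replicate number as the marker. TFAP2C means run from 10.90 in the control to 8.99 with siRNA 2, and the CDKN1A mean is highest with siRNA 2 at 11.73.

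The comparison of siRNA 1 with the non-silencing siRNA asked which transcripts change with that sequence. Genes of mitosis fell, among them TOP2A, the topoisomerase that untangles DNA (-1.21 ± 0.13), the spindle kinesin KIF11 (-1.20 ± 0.21) and the cyclin CCNB1 (-0.99 ± 0.17). Of 40 measured genes of the G2/M and mitosis list, 29 fell and 0 rose, and 39 fell when adjusted over the list alone (median change -0.74). EGR3, an oestrogen-induced transcription factor, fell by 1.39 on the log2 scale, and the keratin genes KRT8 (-0.90 ± 0.16), KRT18 (-0.67 ± 0.14) and KRT7 (-1.02 ± 0.24) fell, which are the 3 luminal markers of 19 that fell, with 6 when adjusted over the list alone and 6 with the replicate block. Of 38 measured G1/S and DNA replication genes 3 fell, with 22 when adjusted over the list alone and 23 with the replicate block. Among genes that moved with siRNA 1 against the control and against both other siRNAs, AKR1C3, a steroid-converting reductase (1.71 ± 0.26), SCUBE2 (1.61 ± 0.10) and the selenium carrier SELENOP (at least 0.94 ± 0.13, from a dim control signal of 6.34) rose, while HGS (-1.47 ± 0.18), the calpain inhibitor CAST (-1.59 ± 0.17) and SPRR1B (-1.53 ± 0.23) fell. These belong to 11 genes higher and 34 lower of that kind.

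With siRNA 1, 517 of 15615 genes passed in limma, 108 higher and 409 lower, of which 19 and 52 changed at least 2-fold. Quantile normalization gave 876 genes, 39.5% of them higher against 20.9%, the replicate block gave 1927 genes, and leaving out the 4 replicate 1 arrays gave 795. The count was 326, 335 and 147 without non-silencing replicates 1, 2 and 3, and 326 without siRNA 3 replicate 3.

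The comparison of siRNA 2 with the non-silencing siRNA held the largest changes among the named genes. CAV1, the main protein of caveolae, rose by 4.58 ± 0.42 (23.9-fold), myosin light chain kinase MYLK by 3.63 ± 0.39, smooth muscle actin ACTA2 by 3.39 ± 0.19 and the steroid dehydrogenase HSD17B6 by at least 3.46 ± 0.19, as its control signal of 6.72 lay below the filter level of 6.82. Dimmer probe sets of ACTA2 (-0.17) and MYLK (0.05) did not rise, while others of CAV1 (3.95), MYLK (5.16) and HSD17B6 (4.03) did. CAV1, MYLK and HSD17B6 also passed against both other siRNAs, as did 210 genes that were higher and 42 that were lower with siRNA 2. Of the latter, RPA1, a subunit of the single-stranded DNA binding protein (-1.68 ± 0.28), the mitotic kinase PBK (-2.09 ± 0.23) and GLRX (-0.98 ± 0.25) fell.

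All 40 genes of the G2/M and mitosis list fell with siRNA 2 (median -1.37), and 40 fell when adjusted over the list alone. Of 38 measured genes of G1/S and DNA replication, 26 fell and 34 fell when adjusted over the list alone, for example the nucleotide reductase subunit RRM2 (-1.80 ± 0.33), RAD51AP1 (-1.55 ± 0.23) and the helicase subunit MCM2 (-1.22 ± 0.23). Of 25 measured p53 targets, 6 rose and 0 fell, and 10 rose when adjusted over the list alone. The risen p53 targets were SESN2 (0.94 ± 0.18), FAS (0.92 ± 0.17), GADD45A (0.89 ± 0.24), PHLDA3 (0.86 ± 0.15), GDF15 (0.79 ± 0.18) and CDKN1A. This list was higher in camera (adjusted p = 2.1e-05), with adjusted p = 0.435 with an estimated correlation. With siRNA 3 the p53 list was lower (median -0.11, camera adjusted p = 0.0384; adjusted p = 0.758 with an estimated correlation). With siRNA 1 it had a median of -0.12 (camera adjusted p = 0.0964; adjusted p = 0.797 with an estimated correlation). With siRNA 1 and with siRNA 3, 0 p53 targets passed. Adjusted over the list alone, 0 fell with siRNA 1 and 2 with siRNA 3, and with the replicate block 5 fell with siRNA 1. Of 14 measured basal and mesenchymal markers, 5 rose, among them ANXA1 (2.59 ± 0.21), CAV2 (2.58 ± 0.27) and the transcription factor SNAI2 (1.93 ± 0.29), and 5 rose when adjusted over the list alone. Among 13 TGF-β and BMP targets, 5 rose, including CCN2 (2.87 ± 0.23), TGFB2 (2.44 ± 0.30) and CCN1 (2.23 ± 0.19), and BAMBI fell (-1.25 ± 0.13). Adjusted over the list alone, 6 rose and 2 fell. The control signals of SNAI2 (6.49) and CCN2 (6.09) lay below the filter level of 6.82, so their changes are treated as lower bounds. ESR1, which encodes the oestrogen receptor, and RET, a receptor tyrosine kinase, are on the list of genes reported as AP-2 targets and fell by 0.52 and 0.58. On that list 3 of 14 measured genes fell and 1 rose with siRNA 2, with the same numbers when adjusted over the list alone.

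With siRNA 2, 1041 genes passed, 515 higher and 526 lower, of which 139 and 131 changed at least 2-fold. Quantile normalization gave 1643 genes and leaving out the 4 replicate 1 arrays gave 1730. The count was 1796 without siRNA 1 replicate 1, 618 without non-silencing replicate 2 and 587 without non-silencing replicate 3.

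With siRNA 3, fewer genes passed. SCD, the desaturase that makes monounsaturated fatty acids, fell (-1.25 ± 0.17), and of the mitosis list 10 genes fell, such as KIF20A (-1.0 ± 0.12) and ASPM (-0.99 ± 0.14), with 30 when adjusted over the list alone and 25 with the replicate block (median -0.53). In G1/S and DNA replication 0 genes passed, also when adjusted over the list alone, at a median of -0.23, and 5 fell with the replicate block. BPIFA1 (2.58 ± 0.44), KLHDC7B (1.46 ± 0.18) and ZBED10P (1.85 ± 0.20) rose with siRNA 3 against the control and both other siRNAs, among 8 such genes. SH3BGRL (-1.11 ± 0.21) and AKAP9, a kinase anchor of the centrosome and Golgi (-0.79 ± 0.12), were the 2 that fell.

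With siRNA 3, 156 genes passed, 66 higher and 90 lower, of which 22 and 20 changed at least 2-fold. Quantile normalization gave 356 genes, the replicate block 686 and leaving out the 4 replicate 1 arrays 305. The count was 38, 42 and 33 without siRNA 3 replicates 1, 2 and 3, 60 and 45 without non-silencing replicates 1 and 3, and 352 without siRNA 1 replicate 1.

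Genes that changed in the same direction with all 3 siRNAs numbered 71, with 17 higher and 54 lower. IGFBP3, which binds insulin-like growth factors, rose by 1.11, 1.29 and 1.34 with siRNA 1, 2 and 3 (standard error 0.19 each). Also among the 10 risen genes with the largest smallest change over the 3 siRNAs were ID4, an inhibitor of helix-loop-helix factors (1.25, 1.10 and 1.16), C11orf96 (1.58, 1.81 and 1.09), the sulfate activating enzyme PAPSS2 (1.14, 1.23 and 0.96), the cadherin CDH26, the activin subunit INHBA (0.91, 0.86 and 1.11), PDK4, which inhibits pyruvate dehydrogenase (0.86, 0.94 and 1.06), MALL, LOC100996740 and ZNF117. A dimmer C11orf96 probe set was flat (0.05, 0.05 and 0.11), and a dimmer ID4 probe set changed less (0.58, 0.52 and 0.48).

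PDZK1, a scaffold protein induced by oestrogen in breast cells, fell by 1.22, 1.75 and 1.21 with siRNA 1, 2 and 3 (standard error 0.20 each). ADIRF (-1.06, -1.35 and -1.64), CDC42EP5 (at least -1.15, -1.16 and -1.05 in size, to dim signals of 5.81 to 5.92), ELAPOR1 (-0.99, -1.75 and -1.32) and the sphingosine 1-phosphate receptor S1PR3 (-0.98, -1.49 and -1.50) fell. So did ASS1, which makes argininosuccinate (-1.21, -1.44 and -0.97), the replication kinase activator DBF4 (-1.13, -1.19 and -0.92), MSMB (-0.92, -1.29 and -1.10), the mitotic kinesin KIF20A (-0.92, -1.66 and -1.0) and carbonic anhydrase CA2 (-1.55, -0.88 and -1.63). From the mitosis list 10 genes fell with all 3 siRNAs, namely CCNB2, CENPE, CENPF, KIF20A, TPX2, TOP2A, CDC20, DLGAP5, PTTG1 and ASPM.

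**Figure D3:**
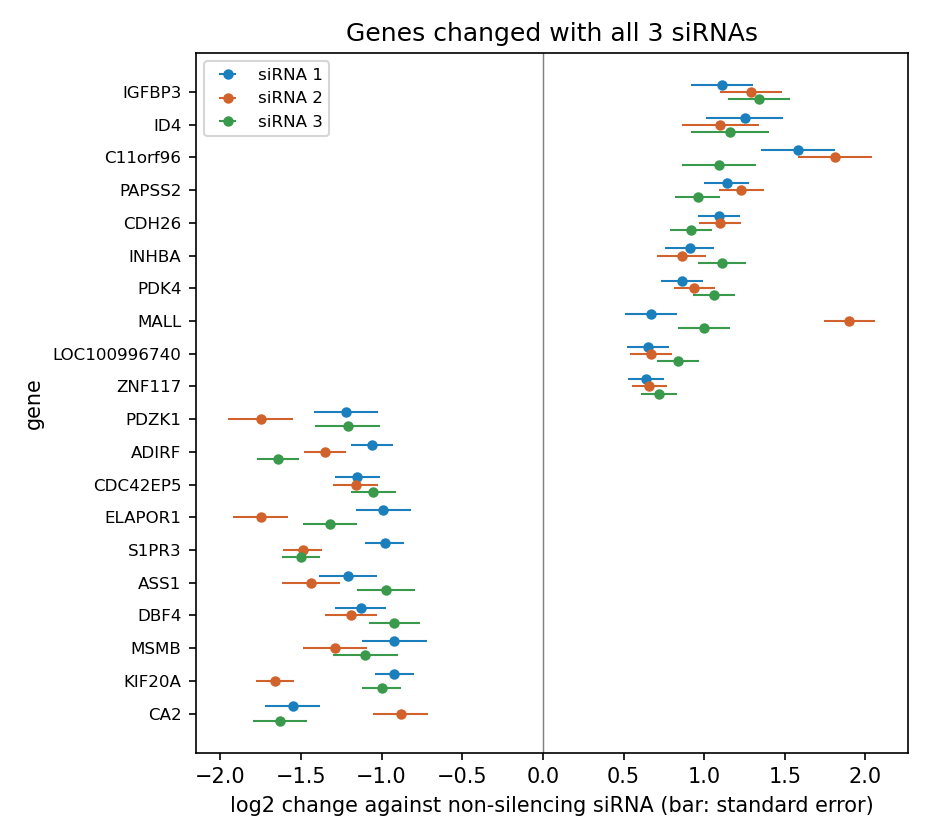
Log2 change against the non-silencing siRNA of the 10 genes that rose and the 10 that fell with the largest smallest change over the 3 siRNAs, with standard error bars, 1 point per siRNA. IGFBP3 lies between 1.11 and 1.34 and CDC42EP5 between -1.16 and -1.05.

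The count of 71 genes was 156 after quantile normalization, with 62 higher and 94 lower (39.7% higher against 23.9%). It was 47 after median centring, 276 with the replicate block and 153 without the 4 replicate 1 arrays, and these 153 hold 60 of the 71. It was 119 without siRNA 1 replicate 1, 24, 26 and 20 without siRNA 3 replicates 1, 2 and 3, and 33 and 18 without non-silencing replicates 1 and 3.

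The 3 comparisons share their control arrays. siRNA 1 and siRNA 2 shared 46 genes higher and 189 lower, where independent lists would share 3.56 and 13.8, and 9 genes moved in opposite directions. siRNA 1 and siRNA 3 shared 24 and 69 (0.456 and 2.36 for independent lists), and siRNA 2 and siRNA 3 shared 39 and 62 (2.18 and 3.03). For all 3 siRNAs independent lists would share 0.015 genes higher and 0.079 lower. In 100 simulations of unchanged groups against the shared controls the count was 0. These simulations held no changed genes, so hardly any gene could pass, and their 0 is no measure of what the shared controls add. Across genes, which are not independent replicates, changes correlated at 0.54, 0.53 and 0.38 for these pairs, against 0.50 in the simulation, and their covariances were 0.0439, 0.0288 and 0.0264 against 0.0139. The 3 control arrays were too few to split, so part of the excess may come from the shared controls.

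The F test among the 3 siRNAs asked which genes responded differently to the sequences. ACTA2 (adjusted p = 1.0e-06), CAV1 (adjusted p = 4.6e-05) and MYLK (adjusted p = 1.5e-04) differed, with the high values on the siRNA 2 arrays. In the mitosis list 28 of 40 genes differed among siRNAs, as did 9 of 25 p53 targets and 5 of 14 basal and mesenchymal markers. In all, 871 genes differed, and 21 of the 71 genes changed with all 3 siRNAs were among them, or 34 with the replicate block. The count was 2781 with the replicate block, 1459 after quantile normalization and 1430 without the 4 replicate 1 arrays. It was 1430 without siRNA 1 replicate 1, 477 without siRNA 2 replicate 2, and 484, 494 and 450 without siRNA 3 replicates 1, 2 and 3.

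Over the 3 siRNA conditions against the non-silencing condition, the mitosis and DNA replication lists were lower. All 40 G2/M and mitosis genes had a lower mean over the 3 siRNAs (median -0.91, camera adjusted p = 6.2e-26; adjusted p = 0.754 with an estimated correlation). Of the G1/S and DNA replication genes 37 of 38 were lower (median -0.60, adjusted p = 7.4e-15; adjusted p = 0.754 with an estimated correlation). Cholesterol and fatty acid synthesis was lower as a list, with 18 of 19 genes below the control (median -0.21, adjusted p = 5.1e-04; adjusted p = 0.754 with an estimated correlation), SCD at -0.66 ± 0.39 and FASN at -0.51 ± 0.23. Luminal epithelial markers were lower (median -0.12, adjusted p = 0.0295, 0.330 after quantile normalization, up to 0.13 with 1 array left out, and adjusted p = 0.754 with an estimated correlation), with PRLR at -0.90 ± 0.50 and KRT8 at -0.73 ± 0.16. Luminal medians were -0.17, -0.15 and -0.06 with siRNA 1, 2 and 3, and 0 markers passed with siRNA 3, or 4 with the replicate block. Basal and mesenchymal markers were higher (median 0.19, adjusted p = 0.0228, 0.0049 to 0.19 with 1 array left out, and adjusted p = 0.754 with an estimated correlation), with CAV1 at 1.57 ± 2.00 and ANXA1 at 1.26 ± 0.87. The rise lay mainly with siRNA 2, as basal medians were 0.09, 0.35 and 0 with siRNA 1, 2 and 3. Of the markers 1, 5 and 0 rose, and with the replicate block 2 rose with siRNA 1. The basal list was higher in camera with siRNA 1 (adjusted p = 0.0400; adjusted p = 0.397 with an estimated correlation). It was higher with siRNA 2 (camera adjusted p = 5.3e-06; adjusted p = 0.0999 with an estimated correlation). With siRNA 3 it had a camera adjusted p of 0.541 (adjusted p = 0.797 with an estimated correlation), with CAV1 at -0.63.

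**Figure D4:**
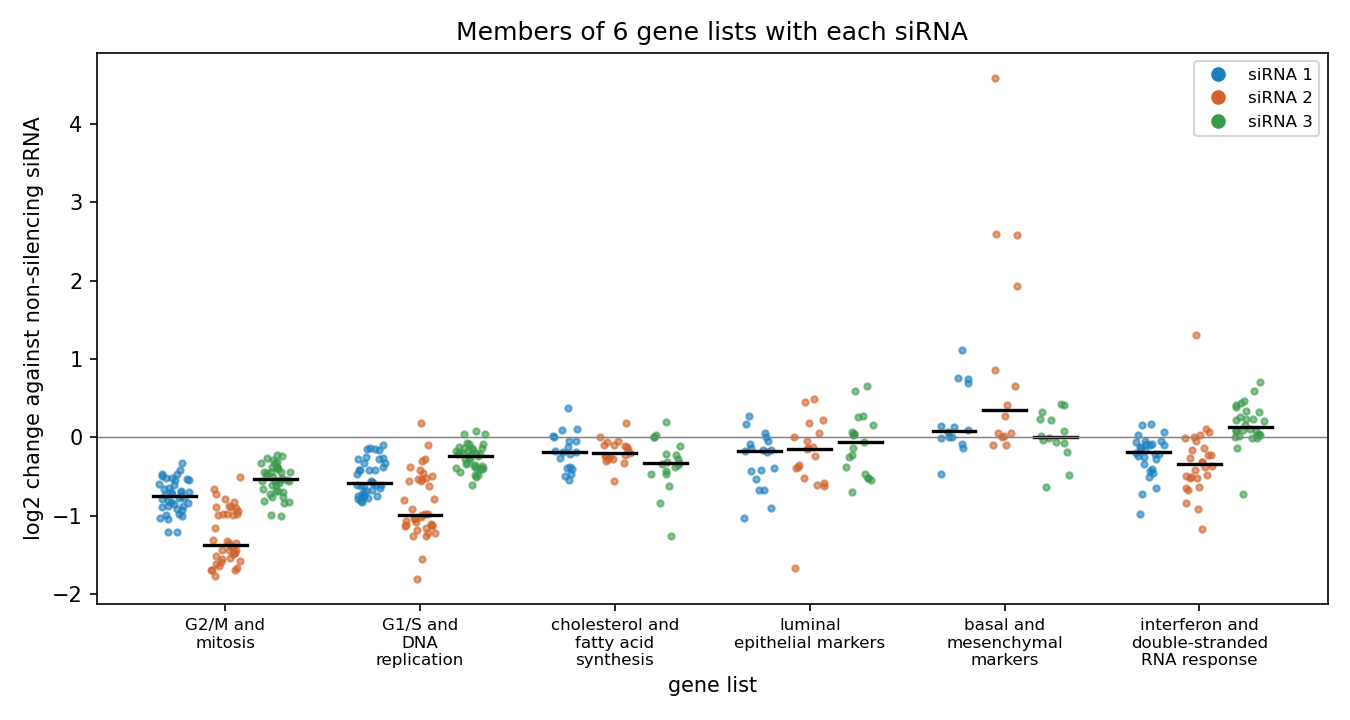
Log2 change against the non-silencing siRNA of the measured members of 6 gene lists, 1 point per gene and siRNA, with a line at the median. Medians of the G2/M and mitosis list are -0.74, -1.37 and -0.53 with siRNA 1, 2 and 3.

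At the level of conditions no single gene passed. limma called 0 of 15615 genes, with 742 at an unadjusted p under 0.05, and the fit with the condition as a random block called 79. TFAP2C had a mean change of -1.27 ± 0.47 and IGFBP3 of 1.25 ± 0.14 in this fit.

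The remaining 14 lists did not pass over the 3 siRNA conditions, and 0 of their members passed at that level. Adjusted over the list alone, 3 genes of the oestrogen response, 1 of the G1 cyclin list and 1 of the TGF-β and BMP list passed. In each list that did pass (mitosis, DNA replication, cholesterol and fatty acid synthesis, luminal and basal), 0 members passed when adjusted this way over the siRNA conditions. The AP-2 family and cofactors gave an adjusted p of 0.273, with CITED2 at 0.51 ± 0.26 and the family member TFAP2A at 0.34 ± 0.18. Genes reported as AP-2 targets gave 0.486, with IGFBP5 at 1.12 ± 0.27 and FREM2 at -0.83 ± 0.34. Other IGFBP5 probe sets were dimmer and changed less, such as 0.48, 0.39 and 0.67, or 0.24, 0.09 and 0.04, with siRNA 1, 2 and 3. The FREM2 change is at least that size, as its signals of 6.17 and 6.47 with siRNA 2 and 3 were dim. G1 cyclins and their kinases and inhibitors gave 0.724, with CCND1 at -0.83 ± 0.14 and CDKN2B at 0.42 ± 0.75. p53 targets gave 0.846, with SESN2 at 0.42 ± 0.36 and TRIAP1 at -0.35 ± 0.20. Apoptosis genes gave 0.724, with PMAIP1 at 0.49 ± 0.38 and BID at 0.36 ± 0.12. The oestrogen response gave 0.358, with PDZK1 at -1.39 ± 0.25 and EGR3 at -0.96 ± 0.30. Receptor tyrosine kinase and MAPK output gave 0.556, with PHLDA1 at 0.84 ± 0.38 and FOS at 0.42 ± 0.21. With siRNA 2 this list was higher (camera adjusted p = 0.00227, or 0.397 with an estimated correlation). Its medians were -0.11, 0.24 and -0.14 with siRNA 1, 2 and 3. TGF-β and BMP targets gave 0.420, with BAMBI at -1.08 ± 0.20 and CCN1 at 1.01 ± 0.80. They were higher with siRNA 2 (camera adjusted p = 0.00783, or 0.296 with an estimated correlation). Their medians were 0.15, 0.26 and 0 with siRNA 1, 2 and 3.

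Hypoxia and glycolysis genes gave an adjusted p of 0.271, with 0.0048 to 0.80 when 1 array was left out and a call in 2 of those 12 settings, with PFKFB3 at 0.68 ± 0.31 and ADM at 0.60 ± 0.14. With siRNA 3 this list was higher (camera adjusted p = 1.9e-04, or 0.758 with an estimated correlation), though 0 members passed. Its medians were -0.05, -0.14 and 0.30 with siRNA 1, 2 and 3. The unfolded protein and ATF4 response gave 0.155, with 0.0316 after quantile normalization and 0.044 to 0.41 with 1 array left out, and had ATF3 at 0.49 ± 0.33 and PPP1R15A at 0.42 ± 0.38. With siRNA 2 this list was higher (camera adjusted p = 4.5e-04, or 0.397 with an estimated correlation). There 5 of its 19 genes rose and 0 fell. Its medians were -0.04, 0.27 and 0.07 with siRNA 1, 2 and 3. SESN2 is both on this list and among the p53 targets. The RNA interference machinery gave 0.425, with DICER1 at -0.37 ± 0.12 and TARBP2 at -0.22 ± 0.13. A second DICER1 probe set of nearly the same signal gave -0.08, -0.04 and -0.21 with siRNA 1, 2 and 3. Interferon and double-stranded RNA response genes gave 0.420, with CCL5 at -0.56 ± 0.40 and XAF1 at -0.50 ± 0.50. Fibroblast markers gave 0.425, with ACTA2 at 1.17 ± 1.43 and COL3A1 at 0.96 ± 0.75. Leukocyte markers gave 0.425, with CD79A at 0.22 ± 0.13 and PTPRC at 0.18 ± 0.18. PTPRC signals of 6.75 in the control and 6.7 with siRNA 3 lay below the filter level.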

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

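All tests of explanations in this part were chosen after the results were seen, except the free regroupings of the arrays.

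The F test found 871 genes that differ among the 3 siRNAs. Of the genes named as targets or by the largest changes with all 3 siRNAs, CDKN1A (adjusted p = 0.00619), MALL (0.00140), ADIRF (0.0454), ELAPOR1 (0.0411), S1PR3 (0.0232), KIF20A (0.00619) and CA2 (0.0282) differed among the sequences. So did 6 other mitosis genes that fell with all 3 siRNAs, CCNB2 (0.00748), TPX2 (0.00113), TOP2A (0.00967), DLGAP5 (0.00352), PTTG1 (0.00129) and ASPM (0.0332). With the replicate block TFAP2C (0.00288), PDZK1 (0.0290), CDC20 (0.0101) and CENPF (0.0425) differed as well, and none of the genes above was lost. MALL rose by 1.90 with siRNA 2 and 0.67 with siRNA 1, and CA2 fell by 0.88 with siRNA 2 and 1.63 with siRNA 3. In 1 of 100 regroupings of the 9 siRNA arrays, the real one, the count was as large, and the highest other was 454. For the 71 genes changed with all 3 siRNAs it was likewise 1 of 100, with a highest other count of 49. Free regroupings ignore the replicate numbers. Of 36 regroupings that keep 1 array of each number in every siRNA group, 1, the real one, was as large for the F test, and the highest other was 315. For all 3 siRNAs 3 of 100 such regroupings were as large. The 2 others had the siRNA 2 arrays as the control, with up to 136 genes. A condition that stands apart can therefore give such a count when it is the shared control. Regroupings whose control mixed conditions gave 0 genes, so they hold little information on the 71. For the F test count chance is excluded only as far as the spread between arrays goes, since the arrays are called technical replicates. For the 71 genes the regroupings do not decide on chance, as those that keep the numbers gave 0 genes with a mixed control. A deviation of the non-silencing condition is not excluded for them either. For siRNA 1 (517 genes, highest other 31), siRNA 2 (1041, highest other 0) and siRNA 3 (156, highest other 0) only 10 splits exist, too few for a share under 0.05, and 1 split, the real one, was as large in each.

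The columns of the reagent-only control repeat the non-silencing columns. Arithmetic means of the deposited non-silencing values match them within 6.5e-09 at every probe set. Separately hybridised arrays with alike expression are excluded, since the SD of the difference is at most 9.3e-10, while siRNA columns differ from any mean of a pair of columns with an SD of at least 0.141. The sum of non-silencing values 1 and 2 was odd at the decimal tested at 25216 probe sets (46.1%). Values calculated before rounding can give odd sums in either direction, so this does not decide which columns were derived. In either case the reagent-only columns add no independent dimension, as the 15 columns have 12. How the columns came to hold means is not recorded, and no biological explanation was tested.

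In each condition the replicate 1 array had the lowest score on the first component. Only with siRNA 1 and siRNA 2 did it lie outside the range of the other arrays. Spike-ins on replicate 1 were lowest in 4 of 4 conditions (means 10.08, 9.73, 10.55 and 10.18 with siRNA 1, 2, 3 and the control). They do not come from the cells, so this goes with a difference in hybridisation or scanning. RNA degradation cannot be told apart from that. The 3′ to 5′ difference was highest on replicate 1 in 5 of 8 condition and gene pairs, 4 for GAPDH and 1 for ACTB. Ribosomal RNA signals, which come from the sample, differed too. On non-silencing replicates 1, 2 and 3 the 18S probe set read 12.46, 8.43 and 8.99, and the 28S probe set 12.75, 10.04 and 10.55. Both were also highest on replicate 1 with siRNA 1 and siRNA 2, but not with siRNA 3. A difference in the RNA samples therefore cannot be told apart either. The labels give no batch or date, and no biological explanation was tested.

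Mitotic genes were lower with every siRNA. A brightness trend of the arrays is argued against, because the list median stayed at -0.85 after quantile normalization, below the lowest of 10000 random lists matched on expression (-0.13). The replicate 1 arrays alone are argued against by a median of -0.84 without them. A step of a single sequence is argued against by the smallest of the medians, -0.53 with siRNA 3. The medians of the 3 siRNAs are all changes from the same non-silencing arrays, so they are not independent. A deviation of that control was not testable, as no second control was measured. A lower AP-2γ level remains an open explanation, as the order of the siRNAs was the same for TFAP2C and the mitosis list, but with 3 sequences the smallest one-sided exact permutation p is 0.167. Fewer dividing cells for any other reason, such as stress from transfection with active siRNAs, was not tested.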

How the results depend on the processing

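The alternatives without the 4 replicate 1 arrays, with all 15 columns and with quantile normalization plus replicate block were chosen after seeing the data. With the replicate number as a block, siRNA 1, 2 and 3 gave 1927, 2524 and 686 genes, all 3 siRNAs 276, the F test 2781 and the contrast over siRNAs in the array fit 1748. Only 5 of 12 arrays correlated best with their own number in every other condition. The block changed none of the 5 list calls over the siRNAs. With quantile normalization as well, the counts were 1705, 2599, 736, 288 and 2876.

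Quantile normalization alone gave 876, 1643 and 356 genes, 156 with all 3 siRNAs and 1459 in the F test, and 156 hold 65 of the 71. Median centring gave 47 with all 3. Probe sets in place of genes gave 1658 for siRNA 2 and 1385 in the F test. A log2 change of at least 1 as well left 6 genes with all 3 siRNAs, by construction. All 15 columns as first planned gave 1058, 1579 and 379 genes, 131 with all 3 siRNAs over 6 comparisons, 1583 in the F test and 3 lists. Without the 4 replicate 1 arrays the counts were 795, 1730, 305, 153 and 1430.

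With 1 array left out, siRNA 1 gave 147 to 679 genes, siRNA 2 gave 587 to 1796, siRNA 3 gave 33 to 352, all 3 gave 18 to 119, the F test 450 to 1430 and the lists 3 (without siRNA 2 replicate 1) to 6. Except where shown by fewer arrays, the cause was not tested. The count over the siRNA conditions was 0 in the fits of condition means that were run, those without an array or a siRNA included. It was 1748 with the replicate block, 597 with arrays as replicates and 79 with the condition as a random block, and quantile normalization with the block was not run for it.

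The number of lists that passed was 2 without the probe sets that may cross-hybridise, and 0 with an estimated correlation in camera or with fry on the condition means. In the other settings 3 to 6 passed, not always the same lists, as after quantile normalization the luminal list was lost (0.33) and the unfolded protein list gained (0.032). Signs turned in values that passed in neither setting. TARBP2 was 0.11 without cross-hybridising probe sets and CDKN2B -0.20 without non-silencing replicate 2 (range with an array left out -0.20 to 0.78). The p53 list turned with fry (adjusted p = 0.99) and without siRNA 1 replicate 1 (0.89), siRNA 2 replicate 2 (0.76) or non-silencing replicate 2 (0.61), within 0.46 to 0.92 over left-out arrays. The kinase and MAPK list turned with fry (0.99) and without non-silencing replicate 2 (0.74, range 0.35 to 0.76), the G1 cyclin list in the array fit (0.94) and the hypoxia list without non-silencing replicate 1 (0.80, range 0.0048 to 0.80). For single genes and lists, 80 planned values lost a call and 30 gained one, while 1867 stayed on their side.

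In the 15-column alternative siRNA 1, 2 and 3 gave 966, 1594 and 341 genes against transfection reagent alone, which is no separate measurement. Reagent alone as control of the condition-level fit was not run for that reason, and a floor before log2 did not apply to log2 values. Seed matches were not searched, as no transcript sequence was available. Signal over background was not used here, so dim genes are limited only by the filter.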

Other observations

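All tests in this part were chosen after the results were seen.

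Probe sets of interferon-induced transcripts gave high signals on the non-silencing arrays, although signals of different probe sets do not compare as abundance. ISG15 had a mean log2 signal of 13.76, IFI27 13.37, IFIT1 13.07 and IFITM1 13.23, and the median of 28 measured list members was 11.16, at the 94.8th percentile of tested genes. The median change of the list over the 3 siRNAs was -0.13, which does not decide whether the AP-2γ siRNAs raise the interferon response, because the siRNAs went both ways. The list was lower with siRNA 2 (median -0.34, camera adjusted p = 0.00633; adjusted p = 0.758 with an estimated correlation). It was higher with siRNA 3 (0.14, 0.0158; adjusted p = 0.797 with an estimated correlation). With siRNA 1 the median was -0.18 (0.0668; adjusted p = 0.810 with an estimated correlation). IFNB1 rose with siRNA 2 (1.30 ± 0.22) and XAF1 fell (-1.16 ± 0.30). Whether transfection itself raises these genes was not testable, because the reagent-only columns hold no measurement of their own.

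Some contractile genes were higher with siRNA 2. After ACTA2, CAV1, MYLK and CCN1 were seen, a list of 14 other smooth muscle and actin cytoskeleton genes was written, of which 13 were measured. Of these 7 rose and 0 fell with siRNA 2, such as TAGLN (3.68), ACTG2 (3.59), TPM1 (2.37) and TPM2 (2.08), while the other 6 did not pass, such as CNN1 at 0.19 and MYL9 at 0.07. A change of the 4 genes alone is argued against by these 7 genes, where the share of all tested genes that rose would give 0.43. The list median of 0.45 does not decide this, as it covers risen and flat members.

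A hypothesis of fibroblast RNA in the siRNA 2 arrays is argued against by a median change of 0.05 over 8 fibroblast markers other than ACTA2, with COL1A1 at -0.12, COL1A2 at 0.08 and DCN at -0.10, although COL3A1 rose by 1.84. A single deviating array is argued against, as the medians of the 13 listed genes on the siRNA 2 arrays were 0.54, 0.61 and 0.51, against 0.01 to 0.03 for each non-silencing array compared with the others. The ratio of the list medians with siRNA 1 and siRNA 2 was 0.18, but with siRNA 1 the members went both ways, with 9 of 13 above 0 and 4 below, so it decides nothing alone. For TFAP2C this ratio was 0.66 ± 0.16. A response in proportion to the TFAP2C reduction is argued against by the slope of the change with siRNA 1 on that with siRNA 2 over all 13 members, which was 0.11 ± 0.10 and between 0.02 and 0.15 with 1 gene left out. With 2 standard errors added, the slope lay just below 0.34, the TFAP2C ratio less 2 standard errors. The standard error of the slope is taken over genes, which are not independent replicates, so this margin is uncertain. The slope was not the only criterion written for this explanation. With siRNA 1, ACTG2 was at 0.31, TPM1 at -0.28, TPM2 at 0.38 and TAGLN at 1.04. With siRNA 3 these genes were at 0.47, -0.44, 0.49 and 1.5, and the list median was 0.03. No slope was taken for siRNA 3. An effect of the siRNA 2 sequence on other transcripts and a response that needs AP-2γ below a threshold remain open and may both apply.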
